A study of Mus musculus with 6 samples.

How the data were processed

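RNA was measured in 6 libraries from hearts of male mice that lack both dystrophin and utrophin (Mdx/Utrn double knockout), a model of Duchenne muscular dystrophy. Per the labels, the mice were 2 to 3 months old at the start, and 3 libraries come from mice that received setanaxib, an inhibitor of the NADPH oxidase Nox4, at 60 mg/kg per day by oral gavage for 12 weeks. The other 3 come from mice that received corn oil, the vehicle. Per the labels' protocols, 1 µg of TRIzol-extracted total RNA went into each library, and libraries were read as paired ends of 150 bases. How RNA was selected, and whether the library preparation keeps strand, is not given in the sources used here.

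The deposited values are estimated counts per gene for 50385 genes in 6 libraries, written as whole numbers and not scaled between libraries by the authors. Expected counts are normally rounded before a count test; these deposited estimated counts were whole already, so no rounding was applied. The design written in advance had assumed raw counts, and the same count tests were kept for these estimates. Per the submitters' processing notes, FastQC 0.11.9, STAR 2.5.4b, featureCounts 2.0.1 and DESeq2 1.42.0 were used with the mouse genome GRCm39, and the notes used here assign no step to a tool. Per the file headers, the row and column names have the form that StringTie's count script writes, a tool the notes do not name. The deposited values themselves point to estimates rather than direct read tallies: each library holds 30 to 40 genes at a value of 1 but 157 to 188 genes at a value of 2. Single libraries can also be at 0 for a gene that holds at least 500 estimated counts in each of the other libraries, which occurred 4 times in setanaxib replicate 1 and 2 times in vehicle replicate 3. Near-identical copies carry near-equal values, so reads that match several places were either counted at each of them or split evenly: the mitochondrial gene mt-Co2 and its nuclear copy Gm28661 differ by at most 0.184% in any library, and Rn7s1 and Rn7s2 by at most 0.773%. Values of genes with a near-identical copy are therefore uncertain, as are those of overlapping genes, because the strand setting of the counting is not given in the sources used here.

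Total estimated counts were 121014814, 154003318 and 132126316 in vehicle replicates 1, 2 and 3, and 142693848, 136772463 and 110803307 in setanaxib replicates 1, 2 and 3. At this depth a gene at 1 CPM (estimated counts scaled to a common library size) rests on more than 100 estimated counts per library, so that the spread between libraries, not counting error, limits most comparisons. Between 21136 and 22253 genes were above 0 per library. Genes of the mitochondrial genome took 20.5% of the total in setanaxib replicate 3 and 30% in setanaxib replicate 1, with the other libraries between these values. With each estimated count taken as 1 read, no pair of libraries matched within sampling noise. A chi-square over genes, divided by its degrees of freedom, was 40.9 or more for every pair. Replicate numbers follow the order of the records and pair no samples; each title carries its own number, which was taken as 1 animal although the labels do not say so in words.

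Counts were analysed in R 4.3.3. Genes were kept with edgeR's filterByExpr at its default minimum of 10 counts, which left 20472 genes, and libraries were scaled by trimmed mean of M values (TMM), with factors from 0.892 to 1.19. The test was edgeR's (4.0.16) quasi-likelihood F test of setanaxib minus vehicle, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were derived from that F statistic, and CPM values are TMM-normalised. Where a symbol labels more than 1 entry, which holds for 80 symbols, the entry with the larger total stands for it in the gene lists. Of the 50385 identifiers, 50110 occur in the reference table used for names and 48606 have the same symbol there; that table is on GRCm38, so no coordinates are given and it served only for names, neighbours and overlaps.

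Before the data were examined, 32 gene lists and 24 lists of cell type or tissue markers were fixed. The 52 lists with 5 or more tested members went through limma's (3.58.1) camera with its preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2, adjusted over all 52. The lists of skeletal muscle, regenerating muscle, lung epithelium and thymus had 4, 0, 3 and 2 tested members and were not tested. For each list, the members were also counted with p adjusted over the list alone, and the test was repeated with an estimated correlation and with fry. Counts over a list alone are not corrected for the 52 lists, and no list member passed edgeR over all genes. The rule for naming genes was fixed at the same time. It took up to 12 genes per direction past the threshold, with an average log2 CPM of at least 0, no overlap between groups and no predicted genes. Where fewer than 10 passed, it filled up to 10 per direction by lowest unadjusted p. It added Nox4, Cybb, Cyba, Dmd, Utrn, Nppa, Nppb, Myh6, Myh7, Acta1, Col1a1, Col3a1, Postn, Tgfb1, Ccn2 and Atp2a2 whatever their values, and the members past the threshold, or up to 4 members of lowest p, from each list described.

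The settings fixed in advance and tried besides these were DESeq2 (1.42.0), limma-voom, robust edgeR, size factors of DESeq2, upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, an adjusted p of 0.1, an absolute log2 fold change of at least 1, removal of mitochondrial and haemoglobin genes, 1 surrogate variable (sva 3.50.0), and each library left out in turn. For lists they were also a prior count of 0.5 and voom weights. The likelihood-ratio test of edgeR, the restriction to genes above 0 in all 6 libraries, and the level of atrial markers as a covariate were added after the data were seen. The steps were tested on simulated counts for the 20472 genes with the means, library sizes and dispersions of the setanaxib against vehicle comparison and 200 changed genes. There edgeR recovered 32% of the genes changed 2-fold and 70% of those changed 4-fold and called 9 of 20226 unchanged genes. DESeq2 recovered 61% and 94%, counted in either direction where the edgeR count required the planted direction, and called 106 unchanged genes. Camera recovered both of 2 planted lists, matrix and macrophage, and called 1 of 49 others. Each gene was drawn independently there, so this count of other calls need not hold for real lists, whose members vary together. The 49 others included the activated fibroblast list, which shares 5 members with the planted matrix list. All columns of the table were used. Some genes that the rule or the lists would name are not reported here.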

Results

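Hearts of Mdx/Utrn double-knockout mice were profiled by RNA sequencing in 6 libraries, 3 after 12 weeks of vehicle and 3 after 12 weeks of setanaxib at 60 mg/kg per day. These mice lack dystrophin, the protein missing in Duchenne muscular dystrophy, and its relative utrophin, and develop a cardiomyopathy. The series asks what part Nox4, an enzyme that makes hydrogen peroxide, plays in this cardiomyopathy, and the design gives 1 comparison, setanaxib against vehicle. Libraries held 110803307 to 154003318 estimated counts over genes, and p-values measure the spread between these libraries, which the labels number but do not call separate animals.

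Dmd and Utrn, the genes mutated in these mice, were read first. Dmd, which encodes dystrophin, was at 124, 125 and 140 CPM in vehicle replicates 1 to 3 and at 178, 151 and 108 CPM in setanaxib replicates 1 to 3. Utrn was at 82.5, 73.7 and 85.7 CPM with vehicle and at 60.8, 75.5 and 106 CPM with setanaxib. Neither differed between the groups in edgeR (log2 fold change 0.17, SE 0.19, adjusted p = 0.877 for Dmd; 0.00, SE 0.21, adjusted p = 0.9996 for Utrn). A whole-gene count includes reads outside the mutated part of a transcript and no wild-type heart is in the series, so these values do not check the genotype. The 14 tested members of the dystrophin-glycoprotein complex, among them Dtnb and Dag1, had a median log2 fold change of 0.03 (camera adjusted p = 0.834).

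Genes of the extracellular matrix, of mechanical stress in heart muscle cells and of macrophages were lower after setanaxib. The lists of the circadian clock and of fat oxidation were higher, though only 10 of 17 clock genes were. Each of these calls was made on a group of genes, by camera with its preset correlation. With an estimated correlation all of these calls were lost (adjusted p = 0.333 for matrix, stress, macrophage and clock genes, 0.708 for fat oxidation), and those of the clock and of fat oxidation also ended in 4 and 2 of the 6 fits without 1 library. Of single genes, edgeR called 1 lower and 0 higher. Among 20472 genes, 1731 had an unadjusted p under 0.05, 770 higher and 961 lower with setanaxib. The groups did not overlap for 17.6% of genes, where chance gives 10%. DESeq2 called 506 genes, 188 higher and 318 lower, and limma-voom called 0. The edgeR count was 0 without vehicle replicate 1, 2 or 3. The excess of lower genes by DESeq2 turned without vehicle replicate 1, 2 or 3, with 329 higher and 206 lower, 378 and 192, and 368 and 215. These fits shared 234, 226 and 263 genes with the 506. Without setanaxib replicate 1, 2 or 3 there were 393 higher and 503 lower, 376 and 610, and 492 and 912.

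On the lower side, Nppb, which encodes the B-type natriuretic peptide that stretched heart muscle releases, averaged 114 ± 37.3 CPM (SD, n = 3) with vehicle and 30.2 ± 6.33 CPM with setanaxib (log2 fold change -1.92, SE 0.28). Loxl2, a collagen cross-linking enzyme, averaged 28.4 ± 0.881 and 18.5 ± 0.495 CPM (log2 fold change -0.62, SE 0.08). Ccl2, the chemokine that draws monocytes, averaged 3.91 ± 1.25 and 0.954 ± 0.106 CPM (log2 fold change -2.03, SE 0.30). Emp1 and Shank1 had log2 fold changes of -0.84 (SE 0.12) and -0.74 (SE 0.11). The other lower genes were 2 pairs of close relatives, the interferon-inducible GTPase Gvin1 with Gm4070 (log2 fold change -0.91 and -0.85) and Gm47283 with Gm21887 (-1.21 and -1.18). Members of such pairs can share reads, which makes each single value uncertain. Loxl2, Shank1, Gvin1 and Gm4070 overlap other genes of the reference, which adds uncertainty because the strand setting of the counting is not given. All genes named in this paragraph had an edgeR adjusted p of 0.234 and did not pass.

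On the higher side, Pim3, a kinase, averaged 25.6 ± 3.90 CPM (SD, n = 3) with vehicle and 52.7 ± 10.1 CPM with setanaxib (log2 fold change 1.04, SE 0.18). Hif3a, a member of the hypoxia-inducible factor family, averaged 1.61 ± 0.548 and 5.33 ± 1.11 CPM (log2 fold change 1.72, SE 0.30). Cfap61, a protein of cilia and flagella, averaged 2.86 ± 0.489 and 8.81 ± 2.08 CPM (log2 fold change 1.62, SE 0.23). Cirbp, the cold-inducible RNA-binding protein, Aox1, Rhobtb1 and Fam214a had log2 fold changes of 0.80 (SE 0.14), 0.84 (SE 0.13), 0.67 (SE 0.12) and 0.88 (SE 0.13). Etfbl, Gm49027 and Gm40604, all under 5 CPM in every library, had log2 fold changes of 3.09, 3.38 and 1.33. Etfbl, from its name a possible copy of the flavoprotein gene Etfb, is uncertain as it can share reads. Pim3, Cfap61, Rhobtb1, Fam214a and Gm40604 overlap other genes of the reference. Their values are uncertain too, because the strand setting of the counting is not given. None of these 10 genes passed edgeR's test, where their adjusted p lay between 0.234 and 0.287.

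**Figure D1:**
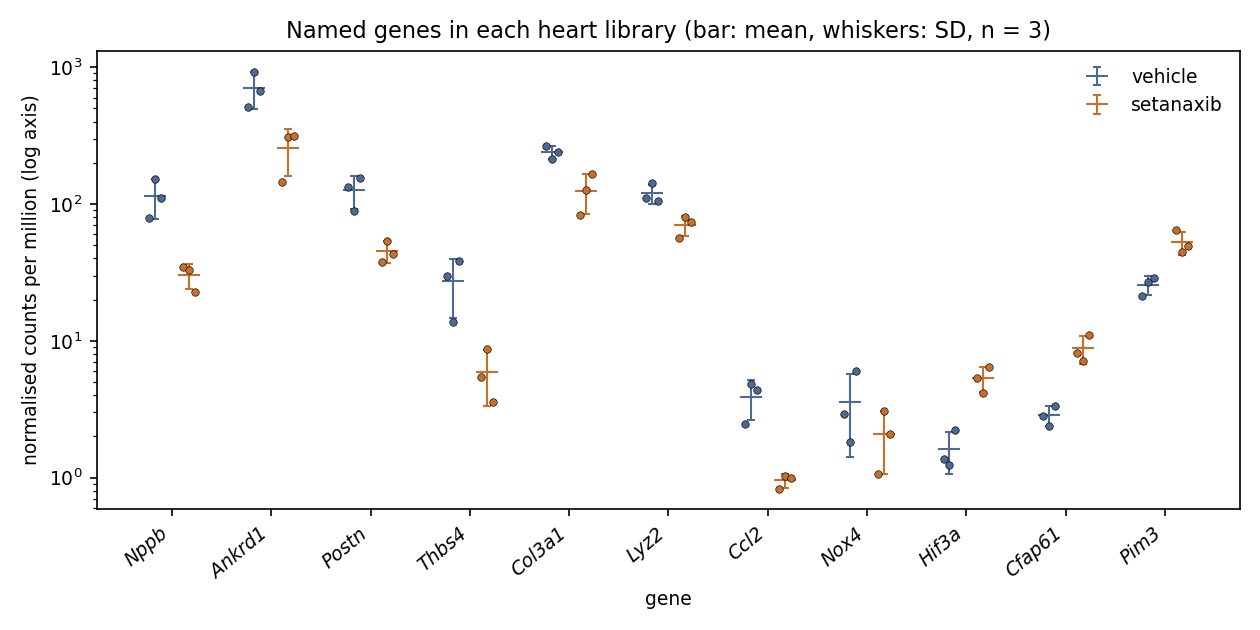
Normalised CPM of 11 named genes (log axis) in each heart library, with points for the 3 replicates of vehicle and setanaxib, bars for means and whiskers for SD. Nppb lies between 78.6 and 153 CPM with vehicle and between 22.9 and 34.6 CPM with setanaxib, while the Nox4 values of the groups overlap.

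Collagens and other matrix proteins fell as a group. Of 30 tested members of the extracellular matrix list, 28 were lower with setanaxib, and 19 passed edgeR when adjusted over the list alone, all lower; over all genes tested, none did, and DESeq2 called 13. The median log2 fold change was -0.63 (camera adjusted p = 1.2e-14; adjusted p = 0.333 with an estimated correlation). Postn, a matrix protein of activated fibroblasts, averaged 126 ± 33.8 CPM (SD, n = 3) with vehicle and 45.1 ± 8.26 CPM with setanaxib (log2 fold change -1.48, SE 0.24). Postn overlaps another gene of the reference, which leaves its value uncertain without the strand setting. Col6a3 and the fibrillin Fbn1 had log2 fold changes of -0.80 (SE 0.13) and -0.62 (SE 0.10), and the main fibrillar collagens Col1a1 and Col3a1 of -0.92 (SE 0.29) and -0.94 (SE 0.25). Every one of these members was lower in all 3 setanaxib libraries than in all 3 vehicle libraries.

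Markers of activated fibroblasts, the matrix-producing state of these cells, fell too. All 10 tested markers were lower, 5 of them past the threshold adjusted over the list alone, with a median log2 fold change of -1.52 (camera adjusted p = 4.9e-06; adjusted p = 0.333 with an estimated correlation). Thbs4 averaged 27.3 ± 12.6 CPM with vehicle and 5.93 ± 2.61 CPM with setanaxib (SD, n = 3), and Meox1, a transcription factor of activated fibroblasts, averaged 22.4 ± 2.67 and 6.96 ± 3.25 CPM. Ddah1 averaged 7.92 ± 0.442 and 4.62 ± 1.06 CPM. The list shares 5 members with the matrix list, and without setanaxib replicate 2 its mean log2 fold change moved from -1.33 to -2.14. General fibroblast markers, led by Pi16, Mfap5, Serpinf1 and Pcolce, had a median of -0.21 (camera adjusted p = 0.0206; adjusted p = 0.695 with an estimated correlation). That call ended without vehicle replicate 1 or 3 (adjusted p = 0.111 and 0.144) and without setanaxib replicate 1 or 2 (0.324 and 0.0516). The mean of -0.28 moved to -0.15 without setanaxib replicate 1 and to -0.44 without setanaxib replicate 3.

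Ligands and response genes of transforming growth factor beta (TGF-beta), the main profibrotic cytokine, fell with a median log2 fold change of -0.30 (camera adjusted p = 0.000969; adjusted p = 0.333 with an estimated correlation). Of 16 tested, 15 were lower and 5 passed when adjusted over the list alone. These 5 were Ltbp2, Tgfb1, Pmepa1, Tgfb3 and Tgfb2, with log2 fold changes of -2.07 (SE 0.47), -0.54 (SE 0.13), -0.55 (SE 0.16), -0.73 (SE 0.21) and -0.77 (SE 0.23). The response gene Ccn2 averaged 154 ± 36.8 and 117 ± 26.6 CPM (SD, n = 3) with overlapping groups. Proteases and inhibitors of matrix turnover, led by Ctss, Timp1, Adamts4 and Mmp2, had a median of -0.23 (camera adjusted p = 0.00637; adjusted p = 0.333 with an estimated correlation), with 13 of 18 lower and 1 past the threshold adjusted over the list alone, Ctss, which is also a member of the macrophage list. Their mean log2 fold change moved from -0.38 to -0.86 without setanaxib replicate 2.

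Stress genes of heart muscle cells, those that rise under pressure load or stretch, fell as a group, with 11 of 14 lower and 5 past the threshold adjusted over the list alone (median log2 fold change -0.71; camera adjusted p = 2.0e-05; adjusted p = 0.333 with an estimated correlation). Besides Nppb, these were Gdf15, Mybpc2, Ankrd1 and Rcan1, with log2 fold changes of -2.27 (SE 0.44), -0.93 (SE 0.19), -1.46 (SE 0.36) and -1.13 (SE 0.30). Acta1, skeletal alpha-actin, averaged 571 ± 76.4 CPM with vehicle and 95.7 ± 73.6 CPM with setanaxib (SD, n = 3), with 10.7 CPM in setanaxib replicate 3. Among the 14, the groups did not overlap for 8 lower members and 1 higher member. Nppa, the atrial natriuretic peptide, went against the list's direction only through setanaxib replicate 3, at 1668 CPM against 64.9 to 523 CPM in the other 5 libraries. It is also an atrial marker, and the atrial markers Myl7 and Myl4 were likewise highest in setanaxib replicate 3. Without that library the list's mean log2 fold change moved from -0.54 to -1.08. The myosin heavy chains Myh6 and Myh7 and the calcium pump gene Atp2a2 had log2 fold changes of 0.03 (SE 0.16), -0.49 (SE 0.42) and 0.23 (SE 0.16), with overlapping groups.

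Nox4 itself, which the labels name as inhibited by setanaxib, was a low transcript. It was at 2.93, 1.82 and 5.99 CPM in vehicle replicates 1 to 3 and 1.06, 3.07 and 2.09 CPM in setanaxib replicates 1 to 3. The log2 fold change of -0.79 (SE 0.55, edgeR adjusted p = 0.765) came with overlapping groups. Of the 12 tested NADPH oxidase genes 10 were lower, and the list fell with a median of -0.50 (camera adjusted p = 0.00767; adjusted p = 0.333 with an estimated correlation). The 3 members of lowest p were Ncf4, Cybb and Rac2, subunits of the phagocyte oxidase, with log2 fold changes of -1.22 (SE 0.36), -0.70 (SE 0.25) and -0.80 (SE 0.30). No member passed when adjusted over the list alone. Cyba, the partner subunit of Nox4 and of Cybb, had a log2 fold change of -0.18 (SE 0.16). The list's call ended without setanaxib replicate 3 (adjusted p = 0.158), and its mean moved from -0.47 to -1.22 without setanaxib replicate 2.

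Macrophage markers fell as a group, with 15 of 16 lower (median log2 fold change -0.82, camera adjusted p = 5.2e-10, adjusted p = 0.333 with an estimated correlation). By edgeR 11 were past the threshold adjusted over the list alone. Over all genes edgeR called none of them and DESeq2 called 8. Lyz2, the lysozyme of myeloid cells, averaged 120 ± 19.2 CPM with vehicle and 70.2 ± 12.0 CPM with setanaxib (SD, n = 3). Ctss, Fcer1g and C1qc had log2 fold changes of -0.87 (SE 0.17), -0.85 (SE 0.18) and -0.52 (SE 0.12). Cytokine, chemokine and adhesion genes fell likewise, with 23 of 24 lower (median -0.75; camera adjusted p = 3.4e-08; adjusted p = 0.333 with an estimated correlation). Their 3 members past the threshold adjusted over the list alone were the monocyte chemokines Ccl2, Ccl8 and Ccl7, at -2.03 (SE 0.30), -1.94 (SE 0.30) and -1.98 (SE 0.46). The list's mean log2 fold change moved from -0.85 to -1.38 without setanaxib replicate 3.

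Interferon-stimulated genes fell with 25 of 26 members lower and a median log2 fold change of -0.47 (camera adjusted p = 5.2e-10; adjusted p = 0.333 with an estimated correlation). The 1 member past the threshold adjusted over the list alone was Mx1, at 0.43 ± 0.0566 CPM (SD, n = 3) with vehicle and at 0 in all 3 setanaxib libraries. This low level is uncertain, because estimated counts can be at 0 for reasons other than absence of the transcript. Rsad2, Isg15 and Ifit1 had log2 fold changes of -0.84 (SE 0.21), -0.80 (SE 0.21) and -0.69 (SE 0.22). Genes of antigen presentation by the major histocompatibility complex (MHC) fell with all 16 members lower and a median of -0.37 (camera adjusted p = 2.7e-06; adjusted p = 0.393 with an estimated correlation). The 6 past the threshold adjusted over the list alone included the class II genes H2-Eb1, H2-Aa and H2-Ab1, at -0.73 (SE 0.16), -0.69 (SE 0.17) and -0.74 (SE 0.19), and the immunoproteasome subunit Psmb10 at -0.50 (SE 0.11).

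A further 7 lists passed downward, each with a call that ended without at least 1 library. Heat shock proteins, led by Hspa1b, Hspa1a, Hspa1l and Hspb6, had all 18 members lower, 3 of them past the threshold adjusted over the list alone (median log2 fold change -0.27; camera adjusted p = 2.1e-05; adjusted p = 0.677 with an estimated correlation). Cell cycle genes, led by Mki67, Foxm1, Cdc20 and Aurka, had a median of -0.55 (camera adjusted p = 8.4e-05; adjusted p = 0.677 with an estimated correlation). Glycolysis, led by Pgam1, Pfkp, Eno1 and Hk1, had a median of -0.20 (camera adjusted p = 0.000743; adjusted p = 0.677 with an estimated correlation), and hypoxia targets, led by P4ha1, Vegfa, P4ha2 and Edn1, a median of -0.24 (camera adjusted p = 0.00967; adjusted p = 0.677 with an estimated correlation). These 4 calls ended without setanaxib replicate 3 (adjusted p = 0.0576, 0.141, 0.205 and 0.192). Without that library the means of heat shock, cell cycle and glycolysis genes moved from -0.37, -0.52 and -0.21 to -0.21, -0.25 and -0.10, and without setanaxib replicate 1 the cell cycle mean moved to -1.10.

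The other 3 lists that passed downward were of complement, vessel wall and lymphatic cells, with 0 members past the threshold adjusted over the list alone and 2, 3 and 3 at an unadjusted p under 0.05. The complement list, led by C7, C5ar1, C3ar1 and C1s1, had a median of -0.37 (camera adjusted p = 0.00917; adjusted p = 0.677 with an estimated correlation). Its call ended without setanaxib replicate 1 or 2 (adjusted p = 0.0843 and 0.0660). Its mean of -0.12 moved to -0.19 and -0.05 without vehicle replicates 2 and 3, and to 0.13, -0.02 and -1.31 without setanaxib replicates 1, 2 and 3. Smooth muscle and pericyte markers, led by Notch3, Cspg4, Vtn and Pdgfrb, had a median of -0.33 (camera adjusted p = 0.00967; adjusted p = 0.333 with an estimated correlation) and lost the call without vehicle replicate 1 or setanaxib replicate 3 (0.0727 and 0.0710), with a mean moved from -0.26 to -0.17 without vehicle replicate 1. Lymphatic endothelial markers, led by Flt4, Mmrn1 and Ccl21a, had 6 of 7 members lower, with Lyve1 at 0.29 (SE 0.13), and a median of -0.50 (camera adjusted p = 0.0175; adjusted p = 0.333 with an estimated correlation) and lost it without vehicle replicate 1 or setanaxib replicate 1 (0.0502 and 0.0540).

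Genes of the circadian clock rose as a list, with 10 of 17 members higher and 4 past the threshold adjusted over the list alone (median log2 fold change 0.84; camera adjusted p = 0.0450; adjusted p = 0.333 with an estimated correlation). These 4 were the repressors Nr1d2, Nr1d1, Cry2 and Per1, with log2 fold changes of 1.21 (SE 0.23), 1.62 (SE 0.41), 0.85 (SE 0.23) and 1.97 (SE 0.52). The clock list did not move in a single direction, as 7 of its members were lower. The groups did not overlap for 6 higher members and 1 lower member. The call ended without vehicle replicate 1 or 2 (adjusted p = 0.0942 and 0.0667) and without setanaxib replicate 1 or 3 (0.0843 and 0.0739). Fatty acid oxidation genes and targets of the receptor PPAR rose with 27 of 28 members higher but a median of only 0.14 (camera adjusted p = 0.00599; adjusted p = 0.708 with an estimated correlation). Acot1, Pdk4 and Ucp3 had log2 fold changes of 1.07 (SE 0.24), 1.97 (SE 0.63) and 1.04 (SE 0.43), and no member passed adjusted over the list alone. The call ended without vehicle replicate 3 or setanaxib replicate 2 (adjusted p = 0.0711 and 0.386), and the mean moved from 0.33 to 0.16 without setanaxib replicate 2.

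Targets of the FOXO transcription factors and of muscle atrophy, led by Klf15, Foxo3, Fbxo21 and Sesn1, rose with 10 of 12 higher and a median of 0.24 (camera adjusted p = 0.0187; adjusted p = 0.536 with an estimated correlation), a call that ended without vehicle replicate 1 or setanaxib replicate 2 (adjusted p = 0.0725 and 0.322). Genes of the glucocorticoid response, led by Hif3a, Pdk4 and Map3k6, rose with 13 of 15 higher, against them Ptgds at -0.95 (SE 0.42), and a median of 0.998 (camera adjusted p = 0.0467; adjusted p = 0.708 with an estimated correlation). This list followed single libraries: its mean deviation was 1.28 log2 units in setanaxib replicate 1 and -0.84 in setanaxib replicate 3. Its call ended without vehicle replicate 1 or 2 (adjusted p = 0.157 and 0.0744) and without setanaxib replicate 1 or 2 (0.917 and 0.127), and the mean moved from 0.87 to 0.12 without setanaxib replicate 1. Pdk4 and Angptl4 belong to both the glucocorticoid and the fat oxidation lists.

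**Figure D2:**
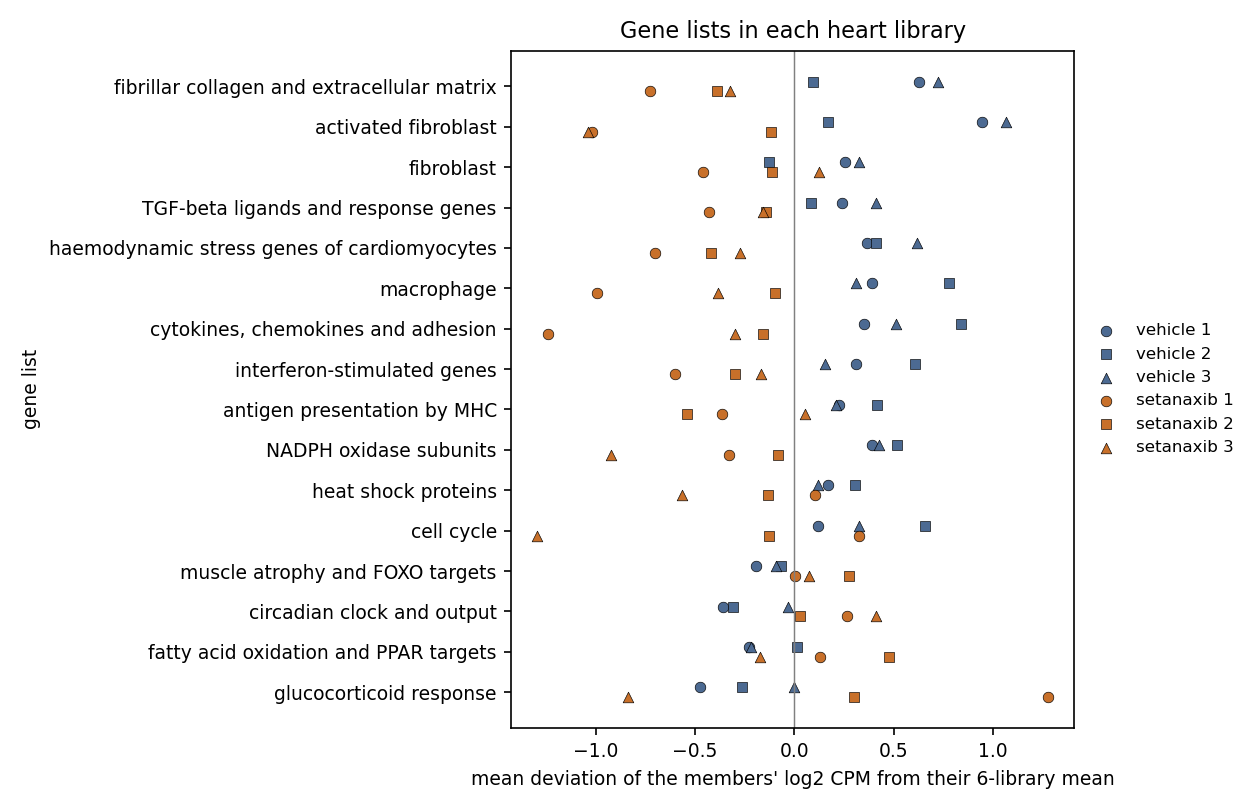
Mean deviation of the members' log2 CPM from their 6-library mean (horizontal axis) for 16 of the fixed gene lists, 1 point per heart library. For the extracellular matrix list the vehicle libraries lie between 0.09 and 0.72 and the setanaxib libraries between -0.72 and -0.33, while for the glucocorticoid response setanaxib replicate 1 lies at 1.28 and setanaxib replicate 3 at -0.84.

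The setanaxib libraries differed among themselves more than the vehicle libraries did. Pearson's r of log2 CPM was 0.960 to 0.964 between vehicle libraries and 0.902 to 0.934 between setanaxib libraries, across genes, which are not independent replicates. Setanaxib replicate 3 was highest for 22 of 30 tested markers of atrium, airway, fat and mesothelium, and the genes of this paragraph were chosen after their values were seen. The atrial light chains Myl7 and Myl4 were at 637 and 609 CPM there and at 23.9 CPM or less elsewhere, the airway secretory protein Scgb1a1 at 598 CPM against 19.6 CPM or less, and the fat marker Car3 at 233 CPM against 7.85 CPM or less. Vehicle replicates 1 and 3 also held more of these transcripts than vehicle replicate 2 and setanaxib replicates 1 and 2. Myl7 was at 23.3 and 21.4 CPM in the former, against 0.103, 0.605 and 1.33 CPM. Scgb1a1 was at 3.89 and 19.6 CPM, against 0.114 CPM or less. The clock output gene Dbp was at 70.7 CPM in setanaxib replicate 3 and at 5.87 to 12.5 CPM in the others. Setanaxib replicate 1 stood alone on the first principal component (38.6% of the variance), at 137 against -61.6 to 12.7. It held 223 genes at least 4-fold below and 61 at least 4-fold above every other library, against 68 and 106 in setanaxib replicate 3. It was also the lowest library for matrix, macrophage and cytokine genes (mean deviations of -0.72, -0.995 and -1.24), lists that passed camera without it as well. There the cell cycle inhibitor Cdkn1a was at 262 CPM, against 7.57 to 32.8 CPM elsewhere. All 22 list calls were lost with an estimated correlation and with fry (smallest adjusted p = 0.333 and 0.0683), and 3 against 3 samples cannot give an exact p below 0.1.

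**Figure D3:**
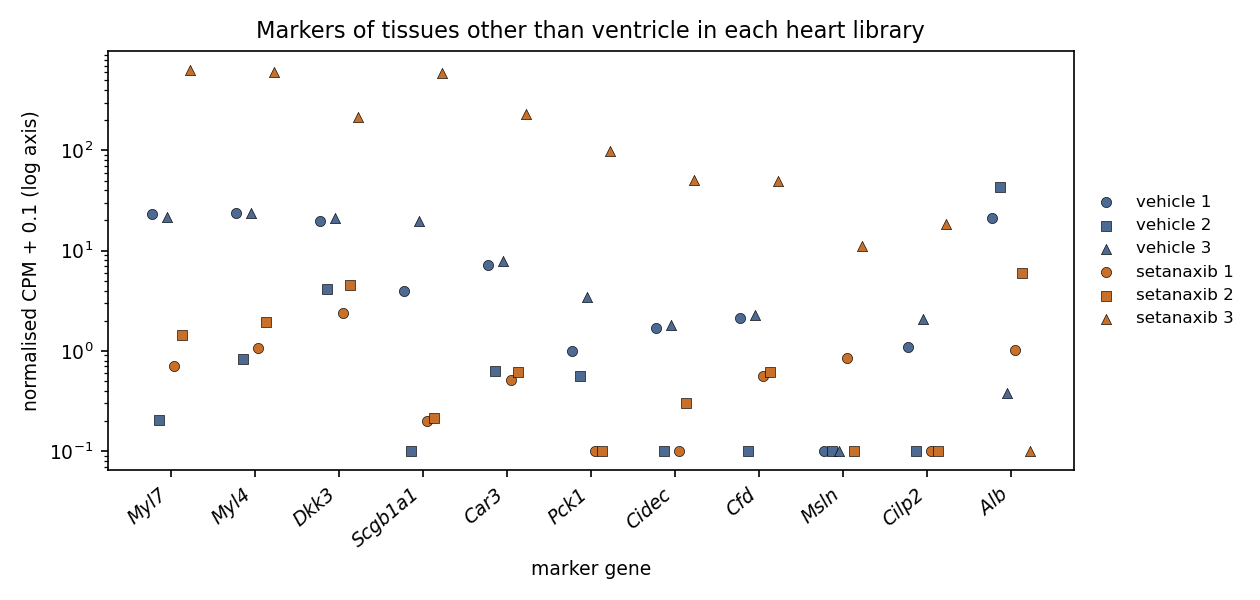
Normalised CPM plus 0.1 (log axis) of markers of atrium (Myl7, Myl4, Dkk3), airway (Scgb1a1), fat (Car3, Pck1, Cidec, Cfd), mesothelium (Msln), cartilage (Cilp2) and liver (Alb), 1 point per heart library. Setanaxib replicate 3 is highest for each marker but Alb, for instance at 637 CPM of Myl7, and vehicle replicate 2 is highest for Alb at 43.3 CPM.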

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

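The likelihood-ratio test, the restriction to genes above 0 in all 6 libraries and the atrial marker covariate were chosen after the data were seen; the other settings were fixed beforehand. The count of genes past the threshold depended on the test. It was 1 by edgeR's quasi-likelihood test, 506 by DESeq2 (188 higher, 318 lower), 162 by edgeR's likelihood-ratio test (52 higher, 110 lower) and 0 by limma-voom (0 lower), where 1731 genes had an unadjusted edgeR p under 0.05; the cause was not tested. It was 1 under every other scaling, filter, threshold or covariate tried with edgeR, and 0 to 1 (0 to 1 lower) over the 6 fits without 1 library, with 0 without vehicle replicate 1, 2 or 3. DESeq2 called 535 to 1404 genes over those 6 fits, with more higher than lower genes in the 3 fits without a vehicle library (329 and 206, 378 and 192, 368 and 215). On the simulated counts, with 200 changed genes, DESeq2 called 106 unchanged genes, more than a threshold of 0.05 allows. Many of the DESeq2 calls may therefore be false. There edgeR called 9 unchanged genes beside 32% of the genes changed 2-fold and 70% of those changed 4-fold. It was thus not shown to keep to that threshold either. Nox4 had a log2 fold change between -1.18 and -0.20 over all settings and never passed. Of the results for named genes, 42 gained the threshold, all by DESeq2 or the likelihood-ratio test, 4 lost it, and none past it changed direction. Genes that never passed could change sign, as Nppa did from 1.14 to -0.03 by limma-voom and -0.51 with 1 surrogate variable. The 22 list calls became 0 with an estimated correlation and 0 by fry. All 22 were kept with DESeq2 size factors, without mitochondrial and haemoglobin genes, with voom weights, genes above 0 in all libraries and the atrial covariate, and 21 with a prior count of 0.5. Over the fits without 1 library 16 to 25 lists were called, with 15 to 20 of the 22 kept. Calls in all 6 of these fits were made for the matrix, matrix turnover, TGF-beta, muscle stress, cytokine, interferon, MHC, activated fibroblast and macrophage lists. Over lists and settings, 631 results kept their side of the threshold, 71 lost and 16 gained it, and 3 past it in either fit turned in direction. Among the 631, 40 means had the opposite sign, as for atrial and fat markers, which turned without setanaxib replicate 3. The 3 past it that turned were nuclear-encoded oxidative phosphorylation (mean log2 fold change -0.10 to 0.18 over the fits without 1 library), the glucocorticoid response (0.12 to 1.19) and the mitochondrial genome (-0.25 to 0.25), where camera's direction turned without setanaxib replicate 1 for the first 2 lists and without setanaxib replicate 3 for the last, past the threshold there for the 2 mitochondrial lists; the cause was not tested. No paired analysis was possible because the labels give each library its own number and the groups share none.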

Other observations

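Several groups of genes tied to oxidative stress and energy supply did not pass the test. Scavengers of reactive oxygen had a median log2 fold change of -0.00 over 20 tested genes (camera adjusted p = 0.772), with only the uncoupling protein Ucp2 at an unadjusted p under 0.05, at 149 ± 9.94 CPM with vehicle and 360 ± 199 CPM with setanaxib (SD, n = 3). Targets of NRF2, the main activator of antioxidant genes, had a median of 0.05 (camera adjusted p = 0.389); Ces1d and Gclc, its members of lowest p, had log2 fold changes of 0.75 (SE 0.20) and 0.52 (SE 0.18). The 42 tested nuclear genes of oxidative phosphorylation had a median of -0.00 (camera adjusted p = 0.834). In the adult sarcomere list (median -0.16; camera adjusted p = 0.280) the titin-cap gene Tcap averaged 280 ± 49.1 CPM with vehicle (SD, n = 3) and was at 504, 447 and 644 CPM with setanaxib (log2 fold change 0.92, SE 0.19), adjusted p = 0.326 by edgeR and 0.000427 by DESeq2. The other lists that did not pass had camera adjusted p from 0.142 to 0.979. The median, mean and test of a list differed in sign for 12 lists, none of them past the threshold.

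The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. By edgeR, 3 of the 10 splits gave as many genes as the real one, which gave 1, and the highest other gave 2. By DESeq2, 1 of the 10 did, the real split itself, with 506 genes against 197 in the highest other. By camera, 2 of the 10 gave as many lists, with 22 in the real split and 26 in the highest other, and no split called fewer than 7. That highest other split, for both DESeq2 and camera, set vehicle replicates 1 and 3 with setanaxib replicate 3, the libraries with the highest atrial marker level. With this level as a covariate, camera called 22 lists and edgeR 1 gene.

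Of the tests that follow, those of setanaxib replicate 3, of fibroblast share and of other tissues were chosen after the result was seen, that of fibroblast share in place of 2 earlier tests of the same markers, while the test of low genes was not. The first pattern is the lower level of matrix, macrophage and muscle stress genes with setanaxib. The fit without setanaxib replicate 3 gave a mean of -1.001 for the matrix list. That library was the highest of the setanaxib libraries for this list (-0.33, against -0.72 and -0.39). The direction of the change on leaving it out was therefore known beforehand. The lower matrix level does not rest on setanaxib replicate 3 alone, but how extra tissue there changed it was not tested. That fit cannot weigh extra tissue in vehicle replicates 1 and 3, where the mean deviation of atrial markers was 0.38 and 0.68. It was -1.63 in vehicle replicate 2 and -2.03 and -0.91 in setanaxib replicates 1 and 2. The matrix deviation was also higher in vehicle replicates 1 and 3 (0.62 and 0.72) than in vehicle replicate 2 (0.09). It was -0.33 in setanaxib replicate 3, the highest library for atrial markers. A lower share of fibroblasts alone, weighed for the matrix genes only, cannot be told apart with 3 libraries per group: activated minus resting fibroblast markers differed by -1.15 (95% interval -2.38 to 0.09; exact p of 0.1, the lowest possible). Also open is an effect of setanaxib on fibroblast activation and macrophage number or state, a hypothesis, and chance differences in disease stage between the 6 hearts.

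The second pattern is the transcripts of other tissues in setanaxib replicate 3. Of 30 tested markers of atrium, airway, fat and mesothelium, 12 (40%) were at least 4-fold above every other library there, and 0 in any other library. This count cannot show the smaller amounts in vehicle replicates 1 and 3, which lie below those in setanaxib replicate 3. A bound of more than 50% of the markers, set at first, was not met, and the comparison with matched genes replaced it afterwards; 20 of the 30 markers are above 5 CPM in vehicle hearts as well. Against 58 of 11693 other genes pooled over the same bins of level, the share was higher (two-sided Fisher's exact p = 6.1e-20). Genes are not independent, and the test was chosen after setanaxib replicate 3 was seen. This p therefore describes the excess and gives no separate evidence for its source. A larger estimate of every low gene is argued against, since only 0.339% of other genes showed such an excess when each bin was weighted by its number of markers. Atrial, airway and fat tissue taken along with this heart is a candidate explanation, and no biological explanation was tested.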
